A study of Mus musculus with 4 samples.

How the data were processed

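Single-cell RNA sequencing libraries were made from mouse hindlimb tissue at day 7 after a dorsal burn of 30% of the body surface with transection of the left Achilles tendon, per the labels. There were 4 libraries: injured and uninjured limbs of mice homozygous for slie, a spontaneous deletion in Ddr2, and of littermate controls. Each library held tissue pooled from 2 mice, per the labels' protocols, so each group had 1 library. The tissue was digested with collagenase and dispase for 20 minutes and passed through a 40 µm strainer, per the labels' protocols. The 10x chemistry, the sequencer, the annotation used for counting and the settings of barcode calling are not given in the sources used here.

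The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 5.0.1 per the file headers and with mm10 named as the genome build per the labels. The values were checked to be whole numbers with different totals per library, over 27998 genes. The deposited barcodes are the ones the authors kept, with smallest totals of 48 UMIs (control uninjured), 500 (control injured), 501 (slie/slie uninjured) and 259 (slie/slie injured), so the limit for a barcode was not the same in each library. Gene coordinates came from the GENCODE annotation of mm10.

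Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept: 751 of 842 barcodes in control injured, 60 of 1075 in control uninjured, 246 of 375 in slie/slie injured and 184 of 289 in slie/slie uninjured. Doublets were scored with Scrublet per library (14, 0, 2 and 4 calls in control uninjured, control injured, slie/slie injured and slie/slie uninjured) and kept in the main analysis. Counts were scaled to 10000 per cell and log transformed, and cells were clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm at resolution 1, all libraries together and without integration, because library and group are the same. Tools were Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1, numpy 2.4.6, R 4.3.3 and edgeR 4.0.16.

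Clusters were named from markers of 22 cell types fixed before the data were examined. A name needed the highest marker score and at least 3 supporting markers. A marker counted when detected in at least 20% of the cluster's cells, at 2 times its median level over clusters or more. The name also needed 1 marker among the 10 leading genes of the cluster or at least 5 supporting markers in all. These thresholds were set after the data were seen, and 1 cluster stayed unnamed under them. The mesenchymal-like clusters differed too much between groups to be joined, under each of several definitions of leading genes that were looked at, so they were compared one by one by number. Leading genes of a cluster are not named as results within that cluster, though some gene lists include them, and cluster sizes are given as descriptions.

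For each comparison and population, UMIs were summed over cells, 1 count was added to each sum, and the ratio of CPM (UMIs scaled to the total of the population) was formed, so that folds refer to the ratio after that addition. Ratios have exact conditional binomial intervals, CPM exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals, all at 95% and for counting error only. No p-values were computed, since cells of 1 library are not replicates. A population needed 20 cells in both libraries. A limit of 10 cells was added after the data were seen. Where 1 sum was 0, a bound against 3 counts is given in place of a fold.

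The 26 gene lists were also fixed beforehand. A member was measured with at least 20 UMIs over both libraries and was counted as higher or lower at 1.5-fold or more. Each list has the median log2 ratio of its measured members, an interval from 1000 Poisson redraws of the counts, and its percentile among 10000 random lists of the same size matched on expression. Members of a random list were drawn independently of each other from the same 2 libraries. The percentile is thus a rank and not a test of genotype or injury, and it is given for some lists only. List examples are the members with the most UMIs. Other genes named in the text were taken, by a rule fixed beforehand, from the 12 highest and 12 lowest per comparison and population among genes with at least 30 UMIs, ranked by the bound of the ratio nearest 1, leaving out mitochondrial, ribosomal, hemoglobin, predicted, Xist and Y-linked genes. Ddr2 was always named. Cwc22, weighed in the closing part, was also among them.

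The method was tested on simulated data, by splitting the pooled counts at known folds and the depths of the real libraries. For the injured genotype comparison, the median recovered log2 ratio was 1.98 for a true value of 2 and 0.01 for unchanged genes, and intervals held the truth for 96.1% of 11263 genes. The simulated counts were Poisson draws from sums over all filtered cells, so the coverage is that of counting error alone. Spread between cells, and populations in which a few deep cells hold most UMIs, were not simulated. With the shallow control uninjured library, the count added to each sum shifted unchanged genes by −0.16 (injury, control mice, where the medians were −1.43 for a true −1, 0.77 for 1 and 1.73 for 2) and −0.09 (uninjured genotype comparison). An alternative with 2 counts shared in proportion to the totals was added for that reason.

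Alternatives chosen beforehand were Leiden resolutions 0.5 and 2, minimums of 100 and 500 genes, at most 10% mitochondrial UMIs, called doublets removed, cells thinned to 500 UMIs by random draws without replacement, equal weight per cell, 0.5 count added, list minimums of 5 and 50 UMIs, TMM scaling with edgeR, totals without transcripts of other cell types, and all barcodes for Ddr2. Chosen after seeing the data were the 2 shared counts, leaving out cells under 0.5% mitochondrial UMIs, leaving out the 3 deepest cells of each population and library, clustering without the control uninjured library, the separate neutrophil-like clusters, the limit of 10 cells and the chondrogenic list without Col11a1. Cells were clustered anew for the minimums of genes, the 10% mitochondrial limit, the removal of doublets and that of the control uninjured library. Each new cluster took the name of the main cluster that most of its cells came from. Clusters that held under 10 cells in a library were not compared, and reads were not realigned.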

Results

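The series compared mice homozygous for slie, a spontaneous deletion in the collagen receptor gene Ddr2, with littermate controls after a hindlimb injury of the kind used to induce heterotopic ossification. Each of the 4 libraries held cells of 1 limb type and genotype at day 7, from tissue pooled from 2 mice: the injured left limb (dorsal burn and tendon transection) and the uninjured right limb. With 1 library per group, no difference between groups could be tested or checked against replicates. All intervals below are 95% intervals that cover counting error only, and folds are ratios of CPM, the UMIs of a gene scaled to the total of the summed cells.

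The libraries differed in depth. The control injured library held 842 barcodes and 4515174 UMIs, the control uninjured library 1075 barcodes and 579790 UMIs, the slie/slie injured library 375 barcodes and 1493147 UMIs, and the slie/slie uninjured library 289 barcodes and 1540053 UMIs. After the filter 751, 60, 246 and 184 cells remained in that order, with medians of 1641, 1337, 1218 and 4841 UMIs per cell. In the control uninjured library 991 barcodes held under 200 genes, so every comparison with that library rested on 60 cells. With a minimum of 500 genes, the slie/slie injured library kept 132 cells. Hemoglobin made up 6.09% of the UMIs in the filtered cells of the control injured library, 10.1% in control uninjured, 5.06% in slie/slie injured and 1.15% in slie/slie uninjured.

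In the injured limbs, Ddr2 transcripts were found in the control library only. Ddr2 (ENSMUSG00000026674, chromosome 1, 169972307 to 170110762, minus strand, mm10) had 116 UMIs over all barcodes of the control injured library, or 25.7 CPM (21.2 to 30.8), and 5 UMIs in the control uninjured library, or 8.62 CPM (2.80 to 20.1). No UMI of Ddr2 was found in the slie/slie injured library, which allows up to 2.47 CPM by the exact Poisson interval. The slie/slie uninjured library had 2 Ddr2 UMIs, both in 1 pericyte or smooth muscle-like cell with 10610 UMIs, whose barcode was in no other library. That is 1.30 CPM (0.157 to 4.69), so the intervals of the uninjured libraries overlap. In the control injured limb most of the transcripts lay in connective tissue and vessel wall cells: 39.2% of pericyte or smooth muscle-like cells (20 of 51, interval 25.8 to 53.9) and 14.9% of mesenchymal-like cells (46 of 308, interval 11.1 to 19.4) held a Ddr2 UMI, at median depths of 2420 and 1371 UMIs. Keratinocyte-like cells held 3 Ddr2 UMIs, in 2 of 31 cells (6.45%), and erythroid-like and monocyte or macrophage-like cells 1 UMI each. Neutrophil-like cells, which should lack the gene, held none in 152 cells at a median of 1213 UMIs, which allows up to 2.40% of cells with a Ddr2 UMI at that depth. The mesenchymal-like cells here join 5 clusters in a different mix, and cluster 1 made up 106 of the 308 control and 21 of the 112 slie/slie cells. In cluster 1, where the median depths were alike (6606 and 6092 UMIs), 33 of 106 control cells (31.1%, 22.5 to 40.9) and 0 of 21 slie/slie injured cells (upper bound 16.1%) held a Ddr2 UMI. The slie/slie injured library held none in all 112 mesenchymal-like cells at a median of 750 UMIs, which is too shallow to bound the share of cells that express the gene. When each cell was thinned to 500 UMIs, the shares were 3.57% of control injured mesenchymal-like cells (1.80 to 6.30), 7.84% of pericyte or smooth muscle-like cells, 0 of 152 neutrophil-like cells and 0 of 79 slie/slie injured mesenchymal-like cells. At that depth the 2 genotypes' mesenchymal-like cells could not be separated by this share, whereas the summed counts over all barcodes of the injured libraries differed beyond counting error.

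The genes on both sides of Ddr2 were present in the slie/slie libraries. Uap1, the annotated gene upstream (170141938 to 170174957), had 62.2 CPM (55.2 to 70) in the control injured and 29.5 (21.4 to 39.6) in the slie/slie injured library, and 27.6 (15.8 to 44.8) and 57.1 (45.8 to 70.4) in the uninjured libraries in that order, so the direction was not the same in the 2 limbs. Hsd17b7, downstream (169949535 to 169969241), had 31.7 (26.7 to 37.3) and 22.8 (15.8 to 31.8), and 5.17 (1.07 to 15.1) and 4.55 (1.83 to 9.37). The last exon of Ddr2 spans 5683 bp, from 169972307 to 169977989. Which part of a transcript was read is not given in the sources used here, so the counts do not map the deletion.

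**Figure D1:**
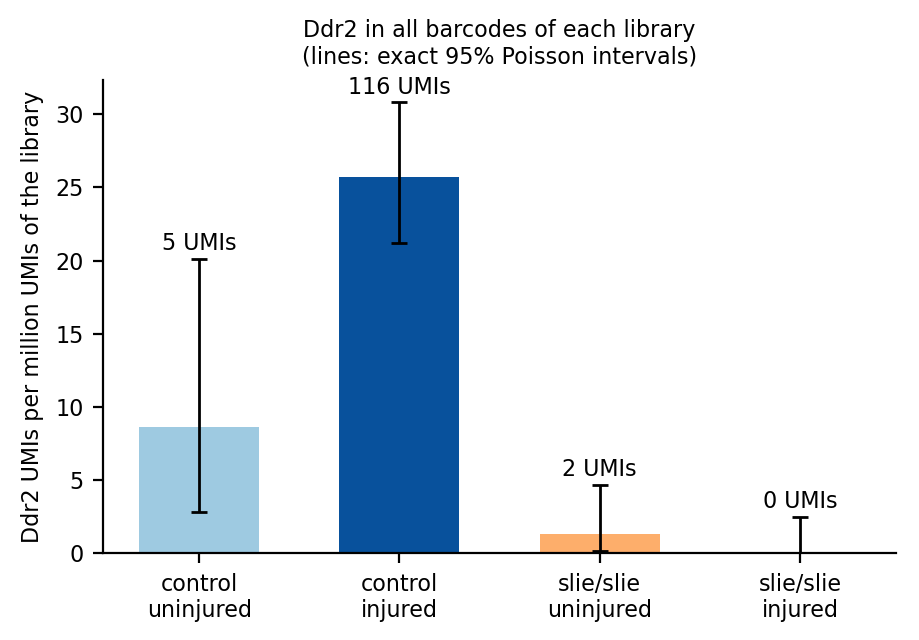
Ddr2 CPM over all barcodes of each library (vertical axis), with 1 bar per library, the UMI count above it and the exact 95% Poisson interval as a line. The control injured library stands at 25.7 CPM with 116 UMIs, and the slie/slie libraries hold 2 and 0.

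Clustering of the 1241 filtered cells gave 17 clusters. Both injured limbs held neutrophil-like, monocyte or macrophage-like, dendritic-like and keratinocyte-like cells, whereas endothelial-like, pericyte or smooth muscle-like and Schwann or glial-like cells were larger classes of the uninjured limbs. The largest class of slie/slie uninjured was the mesenchymal-like cluster 8, with 67 of 184 cells (36.4%), against 2 of 60 in control uninjured. Its 10 leading genes hold 5 myofibre markers (Mylpf, Tnnt3, Tnnc2, Ckm and Acta1) and 1 mesenchymal marker. The erythroid-like cluster has the T cell genes Cd3g and Cd2 among its 10 leading genes, and T or NK markers scored second. In control injured, 16 of its 24 cells held under 0.5% mitochondrial UMIs. Their median was 233.5 genes, against 1529.5 in the others, so this class may mix red cells with other cells. Neutrophil-like cells made up 20.2% (17.4 to 23.3) of control injured and 17.9% (13.3 to 23.3) of slie/slie injured cells, and 0 of 60 (up to 5.96%) and 1.63% of the uninjured cells. Endothelial-like cells were 28.3% of control uninjured and 26.6% of slie/slie uninjured cells, against 3.46% and 2.03% in the injured limbs. The control uninjured share was 43.5% with at most 10% mitochondrial UMIs. The slie/slie uninjured share was 42.9% when clustered without the control uninjured library. Schwann or glial-like cells were 21.7% and 8.70% of the uninjured cells of control and slie/slie mice, 0 of 751 in control injured (up to 0.490%) and 0.407% in slie/slie injured.

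Monocyte or macrophage-like cells were 15% (12.6 to 17.8) of the control injured cells and 6.10% (3.45 to 9.86) of the slie/slie injured cells. Keratinocyte-like cells were 4.13% and 8.94%. These shares are descriptions of the clusters, because the genes that lead a cluster also differed between the injured libraries: the interval of the ratio excluded 1 for 6 of the 10 leading genes of the main monocyte or macrophage-like cluster and for 9 of 10 of the keratinocyte-like cluster. At Leiden resolution 0.5 the monocyte or macrophage-like shares were 21.3% and 14.2%. A sum that uses no cluster gave the same direction: 9 macrophage markers, among them Adgre1, Csf1r, Cd68, Mrc1 and the complement genes C1qa, C1qb and C1qc, had 999 CPM over all barcodes in control injured and 135 in slie/slie injured, a ratio of 0.136 (0.117 to 0.156). Hemoglobin was a larger part of the slie/slie total (33.3% against 15.5%), which lowers this ratio, and no ratio without hemoglobin was computed. The markers were chosen after the data were seen, by leaving out those shared with other classes. Without cells under 0.5% mitochondrial UMIs, the neutrophil-like shares were 6.18% and 4.26%, and the keratinocyte-like shares 1.34% and 2.13%. The monocyte or macrophage-like share rose to 23.4% in control injured, and that of slie/slie injured stayed within its interval.

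**Figure D2:**
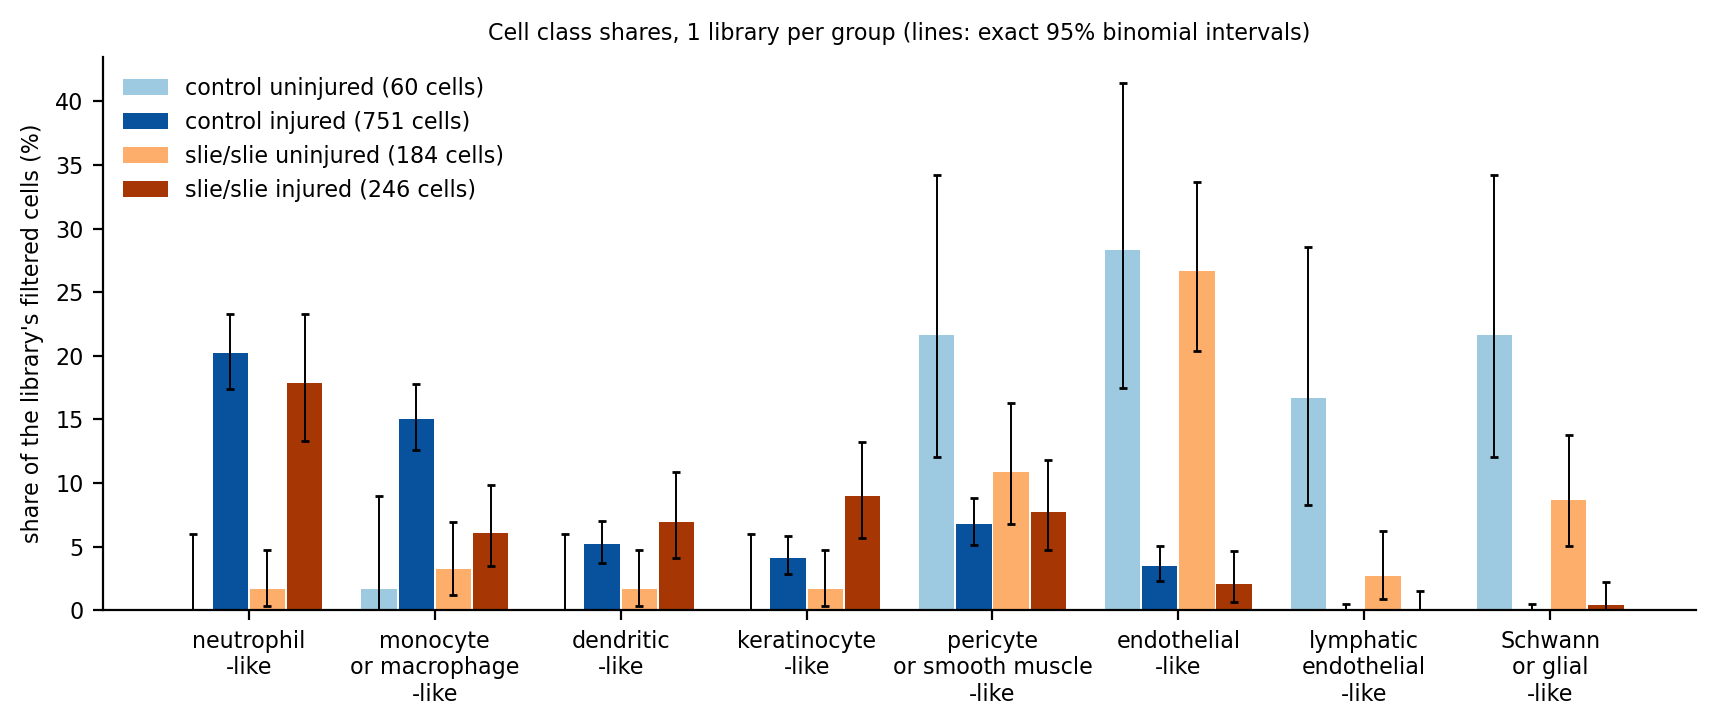
Share of each library's filtered cells (vertical axis, percent) in 8 named cell classes, with 1 bar per library and exact 95% binomial intervals as lines. Neutrophil-like cells are a large share of the injured libraries only, monocyte or macrophage-like cells of the control injured library, and endothelial-like and Schwann or glial-like cells of the uninjured libraries.

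The comparison of the injured limbs addresses loss of Ddr2 at the injury site. Chondrogenic genes were lower in the slie/slie library in the mesenchymal-like cluster 1 (21 slie/slie and 106 control cells). Cluster 1 held 11 of the mesenchymal markers, but none of them was among its 10 leading genes, which include Prg4, a marker of synovial lining, and tenocyte markers scored second. The interval of the ratio excluded 1 for 9 of these 10 genes, 7 of them lower in slie/slie, so the genes that define the cluster moved as well. The median log2 ratio of the 7 measured chondrogenic genes was −1.24 (−1.73 to −0.77), and 6 of the 7 were lower by at least 1.5-fold. Comp, a cartilage and tendon matrix protein, had 8 UMIs against 283 and was 7.46-fold lower (4.19 to 19.6). Acan, the main cartilage proteoglycan, was 2.44-fold lower (1.61 to 4.26), and Sox9, the master regulator of cartilage, 1.54-fold lower with an interval that includes 1 (0.987 to 2.75). Of 10000 random lists of the same size and expression, 0.01% lay as low, a rank within these 2 libraries that does not test genotype. Without Col11a1, which is itself a leading gene of cluster 1, the median was −1.24 over 6 genes. In cells thinned to 500 UMIs the log2 ratio of Comp was −0.26, and Sox9 was −1.68 without the 3 deepest cells.

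Fibrillar collagens were close between genotypes in cluster 1, with a median log2 ratio of −0.15 (−0.50 to −0.11) that turned to 0.04 in thinned cells. Their list includes Col11a1, a leading gene of the cluster. Col1a1 was 1.09-fold lower (1.07 to 1.12) and Col3a1 1.59-fold lower (1.52 to 1.67) in slie/slie, and without the 3 deepest cells Col1a1 stood at 0.25. Glycolysis and hypoxia genes had a median of 0.29 (0.11 to 0.47) with 4 of 16 higher, among them Pgk1 at 2.99-fold (1.99 to 4.42) and Eno1 at 1.61-fold (1.33 to 1.93). Eno1 turned to −0.99 on the log2 scale in thinned cells. Immediate early genes had a median of −0.60 (−0.98 to −0.37) with 10 of 18 lower. In that list Jun was 1.53-fold lower (1.13 to 2.20) and Junb 2.08-fold lower (1.48 to 3.18), and without the 3 deepest cells these were −1.80 and −0.15. Fos had 0 UMIs against 112, at least 8.82-fold lower. The list includes genes that rise during tissue dissociation.

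Single genes with large differences in cluster 1 included Wif1, an inhibitor of Wnt signalling, with 50 UMIs against 6 (30.8-fold higher, 15.1 to 101), and the anion transporter Slc26a7 with 33 against 6 (20.6-fold, 9.63 to 67.9). The EGF receptor ligand Ereg was 10.8-fold higher (5.36 to 26.5), Bmp4 8.46-fold higher (4.01 to 21.1) and the arginine synthesis enzyme Ass1 13.6-fold higher (8.14 to 26.0). Ankrd1, a YAP target, was 23.6-fold higher (16.1 to 38.0) but −0.52 on the log2 scale without the 3 deepest cells. The protease inhibitor Slpi was 8.49-fold lower (6.26 to 12.5) and the hyaluronan-binding protein Tnfaip6 5.53-fold lower (3.94 to 8.59). With cells weighted equally the log2 ratios were −1.12 for Slpi, −0.76 for Tnfaip6 and 2.34 for Ass1. Ddr2 had 0 UMIs against 62, at least 4.88-fold lower. Inflammatory genes (median −0.62) and tendon genes (median 0.32, with Thbs4 3.52-fold higher) gave no stable direction in cluster 1. The tendon list includes Col12a1 and Tnc, which are leading genes of the cluster. The inflammatory median turned to 0.41, and the tendon median to −0.31 and Thbs4 to −1.35, without the 3 deepest cells, which held 63.8% of the slie/slie UMIs of the cluster.

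**Figure D3:**
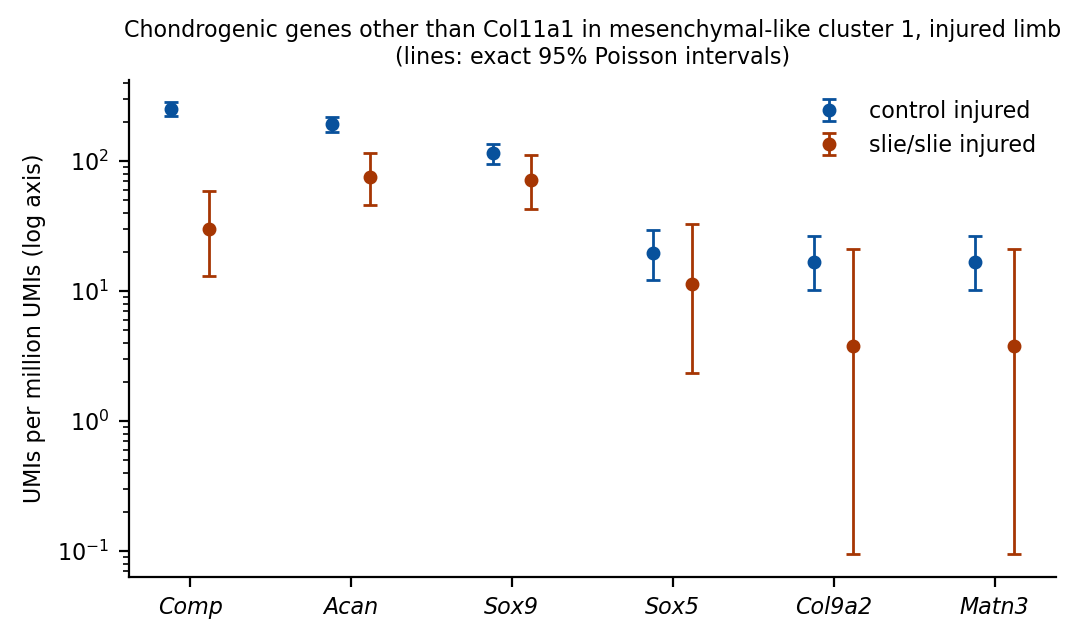
CPM (vertical axis, log scale) of the 6 measured chondrogenic genes other than Col11a1 in mesenchymal-like cluster 1 of the 2 injured libraries, with exact 95% Poisson intervals as lines. Each gene lies lower in the slie/slie library, and the intervals of Comp and Acan do not overlap.

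In the mesenchymal-like cluster 0 (56 slie/slie and 121 control cells), the medians of the focal adhesion and actin list and of the activated fibroblast list were above 0, but not under each alternative. The focal adhesion and actin list had a median log2 ratio of 0.63 (0.34 to 0.91) with 8 of 15 higher, and the activated fibroblast list 0.56 (0.17 to 0.78) with 5 of 11 higher. Tagln was 2.99-fold higher (2.17 to 4.12) and smooth muscle actin, Acta2, 1.84-fold higher (1.42 to 2.36). The secreted peroxidase Gpx3 was 4.30-fold higher (2.17 to 9.09). S100a4 was 5.10-fold lower (2.72 to 14.7), haptoglobin, Hp, 3.45-fold lower (2.05 to 7.35) and the fatty acid carrier Fabp4 3.56-fold lower (2.04 to 8.30). Of the 10 leading genes of the cluster, 9 had an interval that excluded 1, 8 of them higher in slie/slie. The activated fibroblast list includes Cthrc1 and Timp1, which are among these leading genes, and no median without them was computed. Its median is therefore not independent of how the cluster was formed. With a minimum of 500 genes the focal adhesion median was −0.06, the activated fibroblast median −0.43, S100a4 0.14, Hp −0.70, Gpx3 1.24 and Fabp4 −4.73. With cells weighted equally the focal adhesion median and Acta2 stood at −0.05 and Tagln at 0.70. Without cells under 0.5% mitochondrial UMIs the activated fibroblast median was −0.18. Clustering without the control uninjured library gave −3.16 for Fabp4.

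In the proliferating mesenchymal-like cluster 7 (22 and 52 cells), inflammatory cytokines and chemokines were lower in slie/slie, with 5 of 5 measured genes lower and a median log2 ratio of −1.38 (−2.54 to −0.87). Cxcl12, a chemokine that retains progenitor cells, was 2.61-fold lower (1.48 to 5.67), the neutrophil attractant Cxcl5 5.97-fold lower (2.48 to 39.2) on 3 UMIs against 42, and Spp1, encoding osteopontin, 1.51-fold lower (1.02 to 2.39). With called doublets removed, Spp1 was higher in slie/slie (1.40) and Cxcl12 stood at −0.50, and clustering without the control uninjured library gave 1.47 and −0.39. Fabp4 had 0 UMIs against 80, at least 14.8-fold lower. The nuclear RNA Malat1 was 20.7-fold lower (14.1 to 35.3). On the log2 scale its ratio shrank to −0.73 without called doublets and to −1.02 when clustered without the control uninjured library. No control injured cell and 2 slie/slie injured cells were called doublets. Both settings clustered the cells anew, so the shifts can come from changed cluster membership. The annexin Anxa5 was 3.33-fold higher (2.25 to 5.11), or 0.85 on the log2 scale without the 3 deepest cells.

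Neutrophil-like cells of the slie/slie injured limb (44 cells against 152) carried more transcripts of glycolysis. The list's median log2 ratio was 0.67 (0.48 to 0.93), with 7 of 14 genes higher and none lower, above all 10000 random lists. Gapdh was 1.91-fold higher (1.68 to 2.17), the lactate exporter Slc16a3 2.02-fold (1.60 to 2.53), Eno1 1.70-fold (1.23 to 2.32) and Tpi1 2.06-fold (1.38 to 3.02). Cd14, the lipopolysaccharide co-receptor, was 3.68-fold higher (3.38 to 4.0), Thbs1, encoding thrombospondin, 5.60-fold (3.97 to 8.16), the transcriptional regulator Id2 4.70-fold (3.15 to 7.22) and G0s2, an inhibitor of lipolysis, 3.2-fold (2.70 to 3.79). Interferon response genes were lower, with 5 of 7 lower, 1 higher and a median of −0.74 (−1.39 to −0.26). Among them Ifitm3 was 3.85-fold lower (2.57 to 6.60) and Isg15 2.03-fold lower (1.36 to 3.38), though Isg15 was −0.33 on the log2 scale in thinned cells. The growth factor Csf3 had 0 UMIs against 59, at least 6.74-fold lower (−2.11 on the log2 scale with a minimum of 100 genes), and Ltb, a cytokine of the tumor necrosis factor family, was 3.8-fold lower (2.27 to 8.09).

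The class joined a cluster led by Cxcr2, Csf3r and S100a8 (cluster 2) and one led by cytokine genes (cluster 6), and the mix differed: cluster 6 held 27 of 44 slie/slie and 47 of 152 control cells. The glycolysis median was 0.69 in cluster 2 and 0.65 in cluster 6 taken alone, at percentiles 99.95 and 99.86 of the random lists. The interferon median was −0.64 in cluster 2, with an interval that holds 0 (−1.31 to 0.13) and percentile 5.59, and −1.79 over only 2 measured genes in cluster 6. Cd14 stood at log2 ratios of 2.49 and 1.20, and Thbs1 at 3.53 and 1.70. The inflammatory list, with a median of 0.63 in the class, was −0.19 and −0.01 in the separate clusters (percentiles 29.73 and 41.65), and it includes genes that lead cluster 6. In it Il1b had a ratio of 1.06 (0.989 to 1.13). Spp1, at 3.36-fold in the class (2.98 to 3.8), turned to −0.84 on the log2 scale in cluster 2.

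Keratinocyte-like cells (22 slie/slie and 31 control) differed in the opposite way in glycolysis. There 14 of 16 genes of the list were lower in slie/slie, with a median log2 ratio of −1.66 (−2.01 to −1.45), and cell cycle genes were higher, with 7 of 9 higher and a median of 1.37 (0.76 to 1.99). Gapdh was 4.27-fold lower (3.44 to 5.48), Pkm 2.83-fold lower (2.09 to 4.08) and Ldha 2.76-fold lower (2.03 to 4.02). Among cell cycle genes Stmn1 was 6.04-fold higher (3.57 to 11.4), Mki67 6.05-fold (3.11 to 14.1), Hmgb2 3.55-fold (2.25 to 5.79) and Cenpf, on 35 UMIs against 3, 21.1-fold (8.62 to 139). The cornified envelope gene Sprr2d had 0 UMIs against 1038, at least 148-fold lower, its relative Sprr1a was 21.5-fold lower (14.4 to 37.6), and the oxygen sensor Egln3 had 0 against 132, at least 18.8-fold lower. The beta-defensin Defb6 was 7.87-fold higher (4.41 to 16.7). The 3 deepest cells held 71.2% of the slie/slie and 59.3% of the control UMIs, and without them the glycolysis median was −0.53, Gapdh −0.98, Pkm 0.38, the cell cycle median and Hmgb2 0.62, Stmn1 1.62, Sprr1a −0.42 and Sprr2d −3.18. Clustering without the control uninjured library gave a cell cycle median of 0.22, with Stmn1 at 1.68 and Hmgb2 at 1.17, and with cells weighted equally Egln3 was −3.25.

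Over all filtered cells of the injured limbs, macrophage repair genes were lower in slie/slie. Of 15 measured macrophage repair genes 8 were lower and none higher, with a median log2 ratio of −0.94 (−1.03 to −0.57). In that list Lgals3 was 1.96-fold lower (1.76 to 2.19), the growth factor Igf1 1.91-fold lower (1.62 to 2.31), Arg1 6.61-fold lower (4.26 to 12.4) and the mannose receptor Mrc1 8.16-fold lower (4.29 to 26.1). The median shrank to −0.21 in thinned cells, where Arg1 turned to 0.59, and Lgals3 stood at −0.09 without the 3 deepest cells. The platelet factor Pf4, a product of tissue macrophages, was 10.9-fold lower (8.18 to 15.5), the macrophage elastase Mmp12 had 0 UMIs against 144, at least 12-fold lower, and the proton pump subunit Atp6v0d2 had 0 against 195, at least 16.3-fold lower. Matrix proteases had a median of −0.66 (−0.83 to −0.47) with 11 of 20 lower, among them Ctsl at 2.27-fold (2.06 to 2.53), Ctsb at 1.77-fold (1.60 to 1.96) and Ctsk, the collagen-degrading cathepsin, at 4.59-fold (3.91 to 5.49). Their median turned to 0.13 without the 3 deepest cells, and in thinned cells Ctsl stood at 0.03, Ctsb at −0.15, Ctsk at −0.48 and Pf4 at −1.49. The chemokine Ccl19 was 69.0-fold higher (35.6 to 222) and the cytotoxic granule gene Nkg7 59.8-fold higher (27.6 to 278), with log2 ratios of 4.20 and 2.01 when cells were weighted equally. With that weighting Ctsk was −0.31 and Atp6v0d2 −3.13. Both are among the osteoclast markers fixed beforehand, and no cluster was named osteoclast-like. Ddr2 had 0 UMIs against 115, at least 9.61-fold lower.

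Across all cells, chondrogenic genes were again lower (median −0.94, −1.62 to −0.68, 6 of 7 lower), with Comp 6.35-fold lower (3.8 to 14.0) and Acan 2.43-fold lower (1.67 to 3.96). In thinned cells their median was −0.09, Comp −1.25 and Acan 0.11. Tendon genes had a median of 0.58 (0.29 to 0.76) with 4 of 8 higher, namely Thbs4 at 4.11-fold (3.46 to 4.87), Tnmd at 1.96-fold (1.37 to 2.72), the tendon transcription factor Scx at 1.73-fold (1.13 to 2.52) and Kera. Thbs4 turned to −1.18 and Tnmd to −0.04 without the 3 deepest cells. Interferon response genes had a median of −0.51 (−0.87 to −0.34) with 7 of 15 lower, and cell cycle genes 0.33 (0.18 to 0.47) with 4 of 21 higher. The mix of cell classes differed between the libraries as well.

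**Figure D4:**
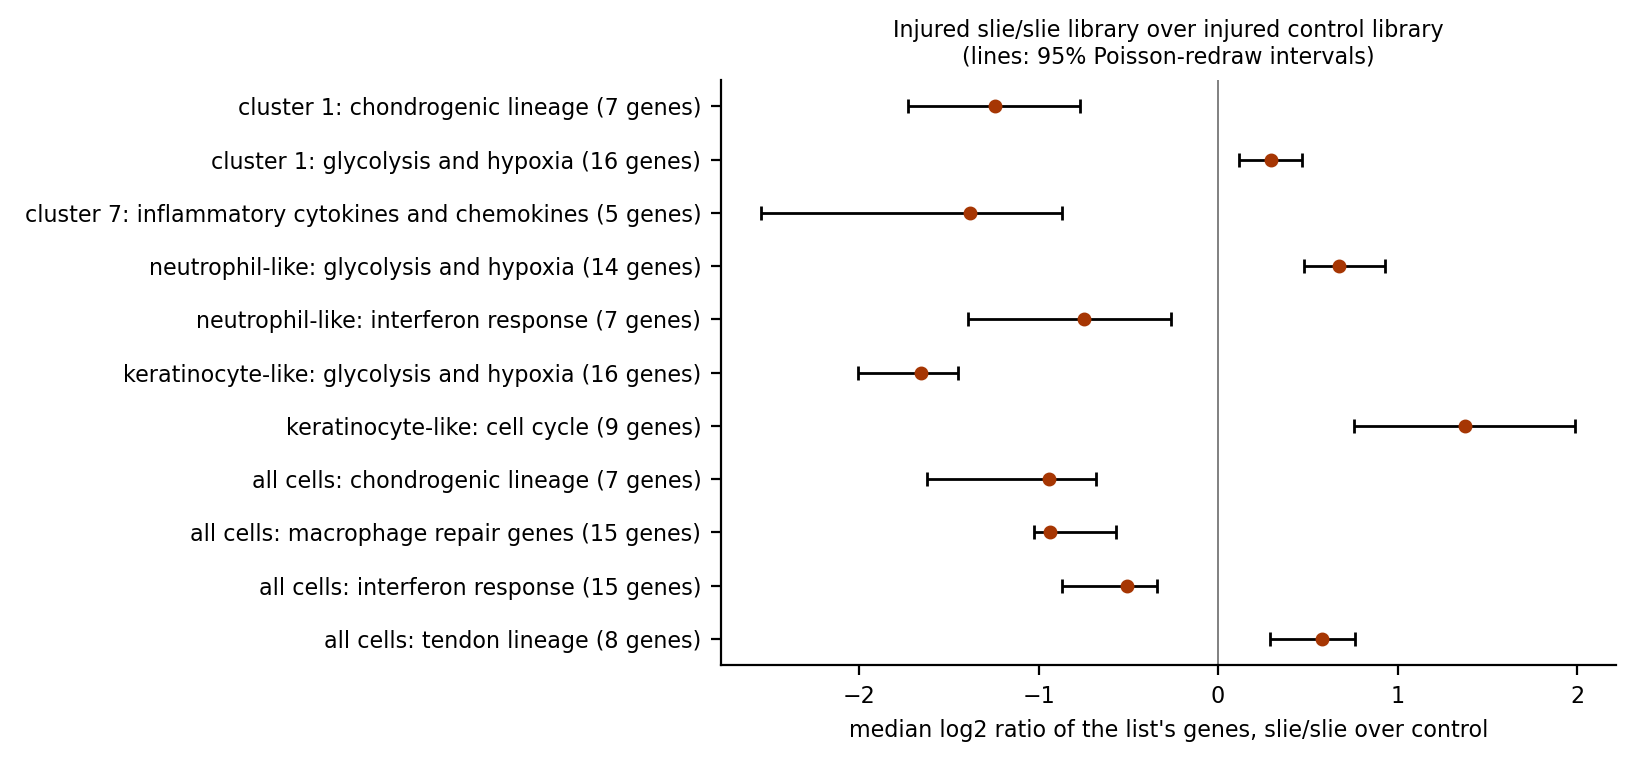
Median log2 ratio of the genes of each list (horizontal axis), slie/slie injured over control injured, for the populations named on the vertical axis, with 95% Poisson-redraw intervals as lines. Chondrogenic genes lie below 0 in cluster 1 and over all cells, and glycolysis genes lie above 0 in neutrophil-like and below 0 in keratinocyte-like cells.

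A limit of 10 cells, added after the data were seen, admitted more classes. In monocyte or macrophage-like cells (15 slie/slie and 113 control), matrix proteases were lower (median −1.33, −2.22 to −0.95, 5 of 7 lower), with Ctsk at 0 UMIs against 1880, at least 34.1-fold lower, and Ctsl 2.52-fold lower (1.91 to 3.56). Inflammatory genes were lower (median −1.34, −1.93 to −0.75, 9 of 13 lower), with Il1b on 3 UMIs against 1652, 22.5-fold lower (10.2 to 145), and Cxcl2 12.4-fold lower (6.34 to 45.7). With genes of 0 counts set at the limit of 3 counts, that inflammatory median was −0.71 (−2.24 with 2 counts shared in proportion to the totals), and at Leiden resolution 0.5 Il1b stood at −1.40. Without the 3 deepest cells Ctsk was −2.80 on the log2 scale, and in thinned cells Ctsl was −0.22 and Cxcl2 −2.12. Ctsk is also one of the fixed osteoclast markers, so its fold is not particular to macrophages. Cluster 4 held 13 of the 15 slie/slie and 83 of the 113 control cells of the class, the other cluster being led by complement genes. The antigen presentation median of 1.53 turned to −0.50 without the 3 deepest cells.

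In pericyte or smooth muscle-like cells (19 and 51), fibrillar collagens had a median of 0.14 with an interval that holds 0 (−0.01 to 0.24), and none of 6 was past 1.5-fold. The interval of Col1a1 excluded 1, with a ratio of 1.13 (1.03 to 1.23). Genes of TGF-beta and BMP signalling were lower (median −0.91, −1.31 to −0.19, 7 of 13 lower and 3 higher), with Id3, a target of BMP signalling, 2.65-fold lower (2.01 to 3.67) and Tgfb1 2.06-fold lower (1.09 to 5.52). The matricellular gene Ctgf, which is not in that list, was 7.94-fold lower (5.29 to 14.0). When cells were weighted equally, the list's median was −0.15 and Id3 was −0.09, and in thinned cells Ctgf was 0.14. The fibrillar collagen median was 0.94 and Col1a1 1.39 without the 3 deepest cells.

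In control mice, inflammatory, macrophage, cell cycle and collagen genes were higher in the injured than in the uninjured limb. Transcripts of neutrophils (10 of 11 higher, median 3.87, 3.74 to 4.62), of skin and fat (5 of 8, median 3.76, 3.28 to 4.73) and of antigen presentation (7 of 12, median 2.78, 2.37 to 3.10) were higher as well. Over all cells 19 of 22 measured inflammatory genes were higher, with a median log2 ratio of 3.69 (3.32 to 4.07). Cxcl2 had 8667 UMIs against 0 (at least 174-fold higher), Il1b 5405 against 0 (at least 109-fold) and S100a9, a neutrophil granule gene, 17027 against 0 (at least 342-fold). Macrophage repair genes had a median of 2.60 (2.31 to 2.98) with 12 of 15 higher, among them Fabp5 at 9.28-fold (7.56 to 11.8). Fibrillar collagens had 8 of 8 higher and a median of 1.69 (1.55 to 1.85), with Col1a1 3.37-fold higher (3.12 to 3.65). Cell cycle genes had 18 of 21 higher and a median of 1.99 (1.58 to 2.32). Interferon response genes were lower (10 of 16, median −1.04, −1.39 to −0.63), with Ly6e 2.44-fold lower (2.10 to 2.80). The progenitor fibroblast list had a median of −0.55 with 8 of 17 lower, and in it Ly6a was 2.53-fold lower (2.18 to 2.90). Over the alternatives that median ranged from −1.18 to −0.07. The endothelial gene Cytl1 had 0 UMIs against 117, at least 648-fold lower.

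The uninjured library's 242888 UMIs limited these sizes. With genes of 0 counts set at the limit of 3 counts, the inflammatory and neutrophil medians were 2.99, the skin and fat median 2.97, the macrophage repair median 1.87, the cell cycle median 1.74 and the antigen presentation median 1.46. The inflammatory median was 2.44 in thinned cells and 5.82 with 2 counts shared between the sums in proportion to the totals. Thinning also gave 1.14 for macrophage repair genes, 1.09 for fibrillar collagens, 0.83 for cell cycle genes (2.81 with the 2 shared counts), −0.39 for interferon response genes and −1.18 for the progenitor fibroblast state. Without the 3 deepest cells the fibrillar collagen median was 3.57, Col1a1 5.48, Fabp5 1.29, the neutrophil median 2.52, the antigen presentation median 1.5 and the skin and fat median 0.38 on the log2 scale. That setting left out the 3 deepest cells of each population, which removed whole classes from the control uninjured library. Gone were its cells of mesenchymal-like clusters 0, 1 and 8 (2, 1 and 2 cells) and its only monocyte or macrophage-like and erythroid-like cells. These values thus reflect the loss of classes as well as of deep cells. The class shares also differed between the libraries, and these sums do not separate the mix of cells from the level within them.

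Pericyte or smooth muscle-like cells of the control injured limb (51 against 13 cells, under the added limit) had more collagen transcript. All 6 measured fibrillar collagens were higher, with a median log2 ratio of 4.11 (3.54 to 4.69), or 3.79 with the gene of 0 counts at its limit. Col1a1 was 15.8-fold higher (10.5 to 28.1), Col3a1 5.56-fold (3.93 to 8.78) and Col1a2 10.7-fold (6.51 to 23.5). Other collagens had a median of 2.38 (2.11 to 2.90), with the basement membrane gene Col4a1 6.10-fold higher (4.47 to 9.10), and periostin, Postn, had 833 UMIs against 2 (40.9-fold, 16.9 to 507). Cell cycle genes were higher in 15 of 15, with Cenpf at 114 UMIs against 0 (at least 5.59-fold) and Mki67 at 92 against 0 (at least 4.51-fold). Their median of 2.99 was 1.58 with the 11 genes of 0 counts at their limit. Acta2 was 3.88-fold lower (3.65 to 4.13), Tagln 8.74-fold (8.09 to 9.45), Myl9 6.50-fold (5.83 to 7.24), the scaffold gene Sorbs2 29.6-fold (18.6 to 53.5) and the calcium pump regulator Pln 25.2-fold (11.3 to 84.4). The focal adhesion and actin list as a whole had a median of −0.26 (−0.62 to −0.00), with 8 of 21 lower and 4 higher, and −1.75 in thinned cells. In thinned cells the fibrillar collagen median was 2.64, Col1a1 2.89 and Postn 2.84. The 3 deepest cells held 65.2% of the uninjured UMIs, and without them that median was 3.29.

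Endothelial-like cells of the control injured limb (26 against 17 cells) had more transcript of collagens other than the fibrillar ones, with 5 of 5 higher and a median log2 ratio of 2.67 (2.36 to 3.55). Col4a1 was 11.6-fold higher (8.12 to 19) and Col18a1 6.34-fold (3.74 to 14.6). Focal adhesion and actin genes were higher in 15 of 20 (median 1.20, 0.92 to 1.49), with Actb 2.94-fold higher (2.60 to 3.35), and cell cycle genes in 8 of 8 (median 1.36, 0.98 to 2.03), with H2afz 2.38-fold higher (1.74 to 3.53). The fenestral diaphragm gene Plvap was 11.4-fold higher (7.42 to 21.3), Lrg1, a modifier of TGF-beta signalling in vessels, 12.8-fold (7.03 to 36.5), and the imprinted gene Mest, on 428 UMIs against 2, 26.5-fold (10.9 to 328). Interferon response genes were lower in 9 of 10 (median −0.90, −1.29 to −0.58), with Ly6e 2.21-fold lower (1.86 to 2.61). The arterial gene Gkn3 had 0 UMIs against 53, at least 95.5-fold lower, Mgp was 15.3-fold lower (12.8 to 18.6) and the tight junction gene Cldn5 6.17-fold lower (4.95 to 7.72). With cells weighted equally, the interferon median was −0.07, Actb 0.80 and Cldn5 −1.18, in thinned cells Col4a1 was 2.14, and Lrg1 stood at 1.30 with at most 10% mitochondrial UMIs and at 5.62 without the 3 deepest cells. The median depths of the cells were 17632.5 and 1635 UMIs, and the 3 deepest cells held 32.5% of the injured and 62.9% of the uninjured UMIs.

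In slie/slie mice, the injured limb also held more inflammatory transcript than the uninjured limb. Over all cells 16 of 22 inflammatory genes were higher, with a median log2 ratio of 3.73 (2.77 to 4.30). Transcripts of neutrophils were higher in 9 of 10 (median 2.97, 2.66 to 3.27) and those of red cells in 5 of 5 (median 2.10, 1.98 to 2.20), the latter at 0.03 with cells weighted equally and 0.35 in thinned cells. Without the 3 deepest cells of each population these medians were 6.20 and 4.41. That setting removed the 3 neutrophil-like and 2 erythroid-like cells of the slie/slie uninjured library, so these classes were gone from it. Cxcl2 was 200-fold higher (136 to 345), Il1b 32.6-fold (24.7 to 46.0) and the interleukin 1 receptor antagonist Il1rn, on 319 UMIs against 3, 86.8-fold (39.1 to 563). Cell cycle genes were higher in 18 of 20 (median 1.82, 1.43 to 2.16), glycolysis genes in 12 of 18 (median 0.96, 0.76 to 1.15), with Gapdh 2.26-fold higher (2.09 to 2.45), and fibrillar collagens in 6 of 8 (median 0.75, 0.59 to 0.89). Genes of the progenitor fibroblast state were lower in 15 of 17 (median −2.22, −2.47 to −1.88), with Gsn 36.5-fold lower (32.6 to 41.2) and Clec3b 110-fold lower (70.1 to 216). Both lead cluster 8, which held 67 cells of the slie/slie uninjured library and 1 of the injured. Skeletal muscle transcripts were lower in 9 of 9 (median −5.76), interferon response genes in 10 of 12 (median −1.13, −1.34 to −0.79), and macrophage repair genes were higher in 6 and lower in 7 of 15 (median −0.41, −0.69 to −0.26). The lymphatic chemokine Ccl21a had 0 UMIs against 680, at least 209-fold lower, and the complement gene C7 0 against 381, at least 117-fold lower. The inflammatory median was 4.84 in thinned cells, where the macrophage repair median turned to 1.00, the cell cycle median was 0.85 (4.55 with called doublets removed and 2.53 without the 3 deepest cells), C7 −4.70 and Ccl21a −5.97, and the inflammatory median was 2.44 over genes with at least 50 UMIs.

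Pericyte or smooth muscle-like cells of slie/slie mice (19 injured and 20 uninjured) also had more collagen after injury. Fibrillar collagens were higher in 6 of 6, with a median log2 ratio of 3.90 (3.43 to 4.44). Col1a1 was 30.2-fold higher (20.8 to 50.0), Col3a1 11.6-fold (8.44 to 17.2) and Col1a2 9.10-fold (6.46 to 13.9). Other collagens were higher in 9 of 9 (median 2.49, 2.03 to 2.98), with Col4a1 4.16-fold higher (3.37 to 5.25), and Postn was 16.3-fold higher (8.98 to 43.1). Cell cycle genes were higher in 9 of 9, with a median of 4.27 (3.46 to 4.90), or 3.14 with the 4 genes of 0 counts at their limit, and with Mki67 at 43 UMIs against 0 (at least 15.8-fold) and Cenpf at 46 against 0 (at least 16.9-fold). Genes of TGF-beta and BMP signalling were lower in 3 of 5 and higher in 1 (median −0.69, −1.51 to −0.23). Sorbs2 was 8.16-fold lower (4.91 to 16.8) and Pln, on 1 UMI against 87, 39.9-fold lower (13.8 to 3149). The 3 deepest cells held 67.9% of the injured UMIs, and without them the fibrillar collagen median was 5.02. With cells weighted equally it was 4.50, and the TGF-beta and BMP median turned to 0.13.

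**Figure D5:**
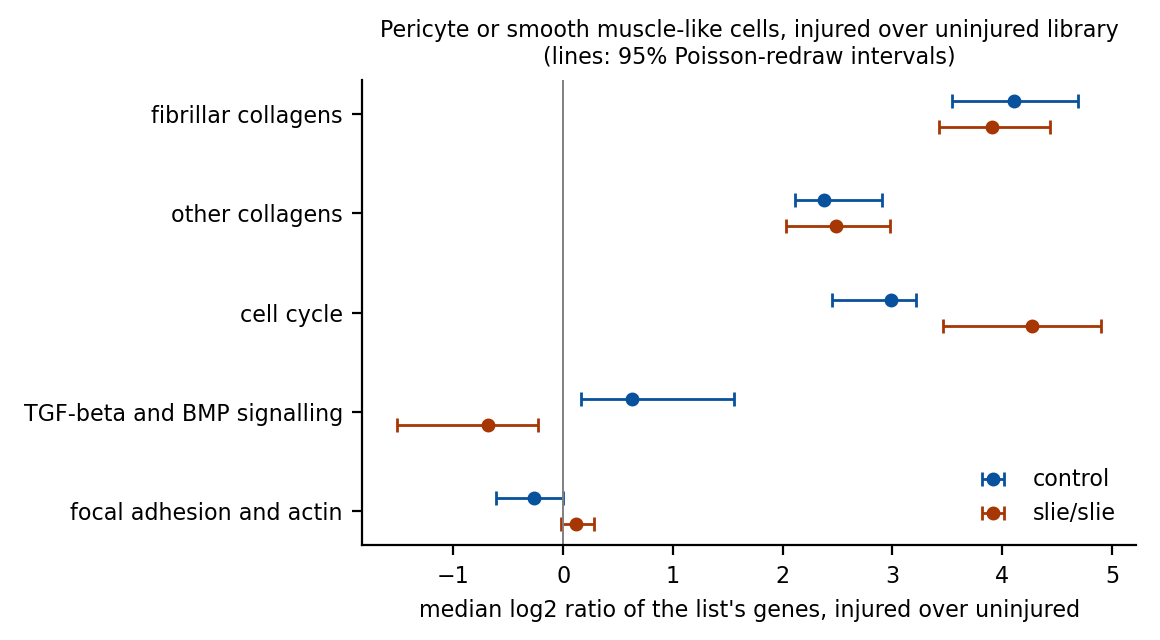
Median log2 ratio of the genes of each list (horizontal axis), injured over uninjured library, in pericyte or smooth muscle-like cells of control and slie/slie mice, with 95% Poisson-redraw intervals as lines. The fibrillar collagen medians stand at 4.11 and 3.90, and those of TGF-beta and BMP signalling at 0.63 and −0.69.

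In the uninjured limb, focal adhesion and actin genes of pericyte or smooth muscle-like cells were lower in slie/slie (20 cells against 13, under the added limit). The 3 deepest cells held 65.2% of the control and 31.8% of the slie/slie UMIs. The focal adhesion and actin list had a median log2 ratio of −0.72 (−0.89 to −0.42), with 9 of 16 lower and none higher. Acta2 was 1.85-fold lower (1.73 to 1.98), Tagln 2.04-fold (1.90 to 2.19), Myl9 2.00-fold (1.80 to 2.23) and calponin, Cnn1, 4.64-fold (3.00 to 7.60). The calcification inhibitor Mgp, on 408 UMIs against 3, was 47.8-fold higher (21.6 to 309) and the mitochondrial gene Ndufa4l2 5.97-fold higher (3.27 to 15.8). In thinned cells Tagln stood at −0.15, Myl9 at −0.24 and Mgp at 4.19, with cells weighted equally Acta2 at −0.21, and without the 3 deepest cells Cnn1 at −1.53.

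Uninjured endothelial-like cells (49 slie/slie and 17 control) differed in single genes. The 3 deepest cells held 62.9% of the control and 21.2% of the slie/slie UMIs, so a few control cells can carry these differences. Gkn3 (34.9-fold, 14.8 to 228, on 3 UMIs against 53), Bmx (12.3-fold, 6.01 to 36.3) and Gja4 (5.58-fold, 3.22 to 10.6) were lower in slie/slie. The water channel Aqp1 had 169 UMIs against 0, at least 21.8-fold higher, and Car4 was 8.61-fold higher (3.76 to 56.1). With cells weighted equally Gkn3 stood at −2.21 on the log2 scale, in thinned cells Aqp1 at 2.97, and with at most 10% mitochondrial UMIs Bmx at −2.17. Transcripts of red cells (median 5.38, 4.88 to 5.86) and skeletal muscle (median 3.12, or 1.98 with the 4 genes of 0 counts at their limit) were also higher in these cells, at 2.29 and 2.00 without the 3 deepest cells. Over all uninjured cells, genes of the progenitor fibroblast state were higher in slie/slie (11 of 16, median 1.54, 1.08 to 2.22), with Gsn 13.1-fold (11.4 to 15.2) and Clec3b 39.7-fold (23.2 to 96.6) higher. Cluster 8, which these genes lead, held 67 slie/slie and 2 control cells, and in thinned cells Gsn stood at 2.69 and Clec3b at 3.31. S100a9 had 742 UMIs against 0, at least 54.8-fold higher. It was 1.35 on the log2 scale without the 3 deepest cells of each population, which removed the 3 neutrophil-like cells of the slie/slie library.

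The difference between the injury folds of the genotypes was formed per list and was not tested. For inflammatory genes over all cells it was 0.03 on the log2 scale, from 3.73 in slie/slie and 3.69 in control. That value moved to 2.41 in thinned cells and −2.12 with the 2 shared counts, so the likeness of the folds was not stable. For fibrillar collagens of pericyte or smooth muscle-like cells it was −0.20, from 3.90 and 4.11, and 1.68 in thinned cells. Cell cycle genes of the same cells differed by 1.28, over 9 measured genes in slie/slie and 15 in control, or by −0.04 with the 2 shared counts and 2.07 with cells weighted equally. Over all cells, fibrillar collagens differed by −0.95 (0.75 in slie/slie and 1.69 in control) and the progenitor fibroblast state by −1.66 (−2.22 and −0.55). The uninjured libraries differed in their mix, with mesenchymal-like cells at 5 of 60 in control and 77 of 184 in slie/slie. These 2 differences thus do not separate that mix from a response to injury. In thinned cells the collagen difference was −0.11, and over the alternatives the progenitor fibroblast difference ranged from −2.16 to −0.97.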

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

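Lists whose injury medians had opposite signs in the 2 genotypes, each with an interval that excludes 0, are given first. Some lists of the same sign differed by more than some of these, such as skin and fat transcripts over all cells (−3.48) and antigen presentation (−2.22). None of these differences was tested, since each rests on 1 library per group. Macrophage repair genes over all cells had a log2 injury ratio of 2.60 in control and −0.41 in slie/slie mice, a difference of −3.02. It was −0.14 in cells thinned to 500 UMIs. The monocyte or macrophage-like share of the injured limbs was 15% in control and 6.10% in slie/slie mice, and how far the share accounts for the difference was not tested. TGF-beta and BMP signalling in pericyte or smooth muscle-like cells had 0.63 in control and −0.69 in slie/slie mice, a difference of −1.32 over different sets of genes (13 measured in control and 5 in slie/slie). The slie/slie median turned to 0.13 with cells weighted equally, so the signs were no longer opposite, and the difference was −0.49. Red cell transcripts over all cells had −0.75 in control and 2.10 in slie/slie mice, a difference of 2.85 (0.03 in slie/slie with cells weighted equally), beside hemoglobin shares of 10.1% and 1.15% in the 2 uninjured libraries. The control uninjured library held 1 erythroid-like cell, with 25307 of the 242888 UMIs of its filtered cells. Its hemoglobin share, and so the control ratio, can rest largely on that cell. Nuclear genes of oxidative phosphorylation over all cells differed by −0.27, from −0.14 in slie/slie and 0.13 in control mice.

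The barcodes under 200 genes were not analysed further. In the control uninjured library 991 barcodes were of this kind, and 62.0% of their UMIs came from hemoglobin genes. The share was 96.4% in the 76 such barcodes of control injured, 96.8% in the 41 of slie/slie uninjured and 93.5% in the 124 of slie/slie injured.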

How the results depend on the processing

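No paired analysis was possible because each group had 1 library of pooled tissue. Over 236 results, 3107 alternatives were computed: 2660 kept the value within the interval of the result (for cells kept, within 1.5 times), 399 moved it outside, and 48 turned the sign where that interval excluded 0, in 27 results. The settings were far from alike. Thinning kept 48, moved 87 and turned 9, equal weight per cell 118, 88 and 10, and leaving out the 3 deepest cells 107, 79 and 11. TMM scaling kept 208, moved 8 and turned 0. The pooled count therefore overstates stability to cell depth. Genes with 0 UMIs in 1 library have an interval open on that side and could not move there. By comparison the sign turned in 44 of 1586 alternatives for the injured limbs between genotypes, 0 of 668 for injury in control mice, 3 of 422 for injury in slie/slie mice, 0 of 230 for the uninjured limbs and 1 of 108 for the difference of injury folds. All values are log2 ratios, slie/slie over control in the injured limbs unless said otherwise. The cause was not tested for any of them.

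Without the 3 deepest cells of each population and library (chosen after seeing the data), the sign turned in cluster 1 for tendon genes (−0.31), fibrillar collagens (0.25), inflammatory genes (0.41), Thbs4 (−1.35), Col1a1 (0.25) and Ankrd1 (−0.52). It turned in keratinocyte-like cells for Pkm (0.38), over all cells for matrix proteases (0.13), Thbs4 (−1.18) and Tnmd (−0.038), and in monocyte or macrophage-like cells for antigen presentation (−0.50). Macrophage repair genes over all cells moved to −0.50. For injury in control mice, inflammatory genes over all cells moved to 2.54 and fibrillar collagens of pericyte or smooth muscle-like cells to 3.29, and in slie/slie mice the same lists moved to 5.03 and 5.02. Over all cells, this setting also removed whole small classes of the uninjured libraries, as given above.

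With each cell thinned to 500 UMIs, the sign turned in cluster 1 for fibrillar collagens (0.037), inflammatory genes (0.98), Eno1 (−0.99) and Col1a1 (0.10). It turned over all cells for Arg1 (0.59), Ctsl (0.029) and Acan (0.11), and in pericyte or smooth muscle-like cells for Ctgf (0.14). Macrophage repair genes moved to −0.21 and glycolysis genes of neutrophil-like cells to 1.00. For injury in control mice, inflammatory genes moved to 2.44 and fibrillar collagens of pericyte or smooth muscle-like cells to 2.64. In slie/slie mice, inflammatory genes moved to 4.84 and macrophage repair genes turned to 1.00. The difference of injury folds moved to 2.41 for inflammatory genes and 1.68 for fibrillar collagens. In the uninjured limbs, the focal adhesion list of pericyte or smooth muscle-like cells moved to −0.31. The share of mesenchymal-like cells with a Ddr2 UMI moved to 3.57% in control injured.

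With cells weighted equally, the sign turned in cluster 1 for fibrillar collagens (0.10), inflammatory genes (0.21) and Col1a1 (0.10), and in cluster 0 for focal adhesion genes (−0.048) and Acta2 (−0.048). It turned for Pkm in keratinocyte-like cells (0.13), Arg1 (0.49) and Thbs4 (−0.10) over all cells, antigen presentation in monocyte or macrophage-like cells (−0.30), and TGF-beta and BMP signalling with injury in slie/slie pericyte or smooth muscle-like cells (0.13). Macrophage repair genes moved to −0.25, fibrillar collagens with injury in slie/slie pericyte or smooth muscle-like cells to 4.50, and the focal adhesion list of the uninjured limbs to −0.23.

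With called doublets removed and the cells clustered anew, the sign turned in cluster 1 for tendon genes (−1.03), Thbs4 (−1.82) and Col1a1 (0.072), and in cluster 7 for Spp1 (1.40). Inflammatory genes moved to 3.31 with injury in control mice. Clustering without the control uninjured library (chosen after seeing the data) turned the same values to −0.92, −1.71, 0.17 and 1.47, and Col1a1 in pericyte or smooth muscle-like cells to −0.15. With it the endothelial-like share of slie/slie uninjured moved to 42.9%.

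With a minimum of 500 genes, the sign turned in cluster 0 for focal adhesion genes (−0.062), the activated fibroblast state (−0.43) and S100a4 (0.14). Macrophage repair genes moved to −1.03, fibrillar collagens with injury in slie/slie pericyte or smooth muscle-like cells to 3.42, the control injured shares of monocyte or macrophage-like cells to 19.2% and of neutrophil-like cells to 16.9%, and the cells kept in slie/slie injured to 132. With a minimum of 100 genes, macrophage repair genes moved to −1.05 and inflammatory genes with injury in control mice to 4.17. Without cells under 0.5% mitochondrial UMIs (chosen after seeing the data), the activated fibroblast state of cluster 0 turned to −0.18 and macrophage repair genes moved to −1.03. The control injured shares moved to 23.4% monocyte or macrophage-like, 6.18% neutrophil-like and 5.91% endothelial-like, and the neutrophil-like share of slie/slie injured to 4.26%.

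In neutrophil-like clusters taken alone (chosen after seeing the data), inflammatory genes turned to −0.19 in cluster 2 and −0.0051 in cluster 6, and Spp1 to −0.84 in cluster 2. With 2 counts shared in proportion to the totals (chosen after seeing the data), inflammatory genes with injury in control mice moved to 5.82, their difference of injury folds to −2.12, and the cell cycle difference of pericyte or smooth muscle-like cells turned to −0.040. With a list minimum of 50 UMIs, macrophage repair genes with injury in slie/slie mice turned to 0.21 and inflammatory genes moved to 2.44. At Leiden resolution 0.5 the monocyte or macrophage-like shares moved to 21.3% in control injured and 14.2% in slie/slie injured, and at most 10% mitochondrial UMIs moved the endothelial-like share of control uninjured to 43.5%.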

Other observations

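All tests in this part were chosen after the result was seen. In the injured limbs, 50.5% (46.8 to 54.1) of control and 61.8% (55.4 to 67.9) of slie/slie cells had under 0.5% mitochondrial UMIs, and neutrophils, which hold few mitochondria, did not account for them alone, as 41.7% of the control cells outside the neutrophil-like class were of this kind. Outside control keratinocyte-like cells, S100a8 and S100a9 made up at most 0.197% of the UMIs of these cells in any other population of either injured library, neutrophil-like cells aside, against 0.661% and 0.693% of the whole libraries. These cells thus did not carry the average share of the library. Whether droplets with free RNA and no cell are a source cannot be told from this. The free RNA itself was not measured, and the library shares include intact neutrophil-like cells. Droplets rich in these transcripts may also have been placed in the neutrophil-like class, which was set aside. In control keratinocyte-like cells (0.861%) free RNA and their own transcripts cannot be told apart either, because such cells can express both genes. Isolated nuclei are an unlikely source in 14 of 16 populations of the 2 libraries, where the nuclear RNA Malat1 was lower in these cells than in the others of the population or of the library, among them control cluster 0, where it was above the others of the cluster (0.147% and 0.0756%) but far below the 2.67% of the other cells outside neutrophil-like cells and cluster 11. In the other 2, control cluster 1 (6.60% and 2.53%, on 5 cells) and control dendritic-like cells (2.54% and 1.92%), and in cluster 11, with 9.29% in control, nuclei and whole cells cannot be told apart, because Malat1 also differs between whole cells and cluster 11 is itself led by the nuclear RNAs Meg3 and Kcnq1ot1.

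Cwc22, a splicing factor gene on chromosome 2 (77881159 to 77946375), had 1011 UMIs in control injured and 26 in slie/slie injured, and 122 and 58 in control and slie/slie uninjured. Of 2117 genes measured in at least 5 populations, 2 (Cwc22 and the processed pseudogene Gm8730) were lower in slie/slie in each by at least 1 on the log2 scale, and 0 were higher. Free RNA in the control libraries is an unlikely source, as Cwc22 CPM differed by at least 14.0-fold between populations of control injured by its counting interval. Loss of Ddr2 in the cells that express it is an unlikely cause, as neutrophil-like cells, with no Ddr2 UMI in the control limb, had a Cwc22 ratio of at most 0.306. A strain or donor variant carried by the pooled mice may stand behind the lower Cwc22 in 8 populations, and cannot be told apart from other causes, because genotype and donor are the same here and the scan picked the gene.

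The lower share of monocyte or macrophage-like cells in slie/slie injured was weighed against the filter and the clustering. Loss of cells with under 200 but at least 100 genes to the filter is an unlikely cause, as with a minimum of 100 genes the share was 5.35% (3.09 to 8.54) in slie/slie and 14.4% (12 to 17.1) in control. The filter was tested in 6 forms, of which 2 excluded it and 4 worst cases did not, and loss of the other barcodes cannot be told apart from fewer cells, because the slie/slie share would be 12.9% (9.47 to 17.1) if each of the 26 that are not red cells belonged to the class, although only 9 of the 67 such barcodes removed at 200 genes held a UMI of the 9 markers below. Cluster assignment may account for part of it and cannot be told apart from fewer cells, because the shares at Leiden resolution 0.5 were 21.3% (18.4 to 24.4) in control and 14.2% (10.1 to 19.2) in slie/slie. The ratio of 0.136 (0.117 to 0.156) of 9 summed markers does not settle this. It can also fall through fewer marker UMIs per cell, or through the larger hemoglobin share of the slie/slie UMIs. Loss of Ddr2 may underlie the difference, but cannot be told apart from variation between mice, dissections or libraries, because there was 1 library per genotype and limb.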
